A study of Mus musculus with 6 samples.

How the data were processed

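Messenger RNA was sequenced from mouse regulatory T cells of 2 groups. The control group came from mice that carry a Cre recombinase with a yellow fluorescent protein (YFP) under the Foxp3 gene, and the deletion group from mice that also carry floxed Rcor1. Per the labels' protocols, CD4+ cells were enriched on a column and YFP+ cells were then sorted from male mice aged 6 to 8 weeks, RNA was purified with RNeasy kits, and libraries were made with a NEBNext Ultra II kit. Per the labels' design text, each group had 3 independent biological replicates and the reads were paired-end Illumina reads. No batch, litter or sorting day is given in the sources used here.

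The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to the library total) with 35275 Ensembl gene identifiers and 1 column for each of the 6 libraries. Alignment with STAR to the mm10 genome is named in the submitters' processing notes. The counting tool, the annotation release and any filter are not given in the sources used here. Columns were assigned to samples by their names, which match the sample descriptions, and 0 columns were left unused.

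Symbols, positions and transcript lengths came from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the identifiers, 34490 matched a symbol and 785 did not, of which 58 were among the tested genes. The library totals behind the FPKM values were recovered from them, because a value times the gene length and the library total is proportional to a whole number of fragments. Of 21898 genes above 0 in any library, 15336 (70.0%) gave whole fragments within a tolerance of 0.01 fragments with the longest annotated transcript, 6561 did so with a length solved from the values, and 1 did not. Library totals were 18538581 to 22349455 fragments, and the recovered fragments summed to 99.91% to 99.92% of these totals. The totals are thus close to the fragments assigned to genes, and the number sequenced may be higher. A gene at 0 in a whole group was given a floor of 3 fragments over the 3 libraries of that group together. Floors cover counting error only, since PCR copies were not told apart.

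FPKM values are not counts, so the main test was limma (version 3.58.1, in R 4.3.3) with an expression trend in the variance, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 11575 genes. Fold changes are deletion over control on the log2(FPKM + 1) scale, which understates the change of low genes. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p under 0.05 with no fold limit. A quasi-likelihood count model on recovered reads had been planned. It was not run, and limma voom on the recovered fragments with median-ratio scaling was added in its place after the data were seen.

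Fixed lists of genes, 30 in number, and the rule for named genes were written before the data were examined. The rule took Rcor1, a panel of 14 further CoREST, Treg and cytokine genes, and the 10 genes that rose and the 10 that fell with the smallest p among those changed at least 2-fold without overlap between groups. Predicted genes, clone names and receptor variable segments were left out of that part. From each list it took up to 4 members past the threshold with the smallest p, or the 2 members with the smallest p where none passed. It gave 108 distinct genes, and genes named outside it are marked as such. Some genes that the rule takes are not reported here. Lists with at least 5 tested members, 29 of the 30, were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation, camera on ranks and fry were the alternatives. With an estimated correlation, adjustment gave many lists the same adjusted p of 0.842, the smallest of any list. Their unadjusted p-values differed, for example 0.06 for ribosomal genes and 0.522 for plasma cell markers, so the shared value does not rank the lists.

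Both limma tests were tested on simulated fragments for 11573 genes at the recovered totals of these libraries, for the comparison of Rcor1 deletion with control. The main test recovered 62 of 100 genes changed by 1.5-fold and 93 of 99 changed by 2-fold. It made 14 false calls, 8.3% of its calls, which is more than the adjusted threshold aims at. Voom recovered 82 and 95 of them, with 5 false calls (2.7%). Simulated genes varied independently of each other, unlike genes of real libraries, so these shares are only a guide.

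The alternatives were leaving out each library in turn, the replicate number as a block, pseudocounts of 0.1 and 5, no filter on low values and a filter at 5 FPKM, quantile normalization, median-ratio scaling, other models of the spread (no trend, robust, array quality weights), and counts at 2-fold and by limma's treat against 1.2-fold. Added after the data were seen were voom, a fit without immunoglobulin and T cell receptor segments and pseudogenes, fits with a trend on transcript length or on GC content removed, and fry with median-ratio scaling. Probe lists for lens, brown fat, intestinal epithelium and neuronal genes were also written after the main results were seen and before these lists were tested. Shares of fragments in a gene set are given as CPM, that is, fragments scaled to the library total without gene length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.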

Results

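Treg cells are CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. Rcor1 encodes CoREST1, the scaffold that joins the histone demethylase Kdm1a to the histone deacetylases Hdac1 and Hdac2. The comparison asks how the transcriptome of Treg cells differs when Rcor1 is deleted in Foxp3+ cells. RNA of 3 control and 3 deletion samples was sequenced. The totals recovered from the FPKM values were 18538581 to 22349455 fragments per library, and between 11275 and 11658 genes per library reached 1 FPKM. Values below are mean FPKM ± SD over the 3 libraries of a group, and adjusted p-values are from limma unless another test is named. Where counts are given with each library left out in turn, they stand in the order of control libraries 1, 2 and 3 and deletion libraries 1, 2 and 3.

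Rcor1 (ENSMUSG00000037896, chromosome 12, 111039351 to 111115901 on the plus strand of GRCm38) was lower in every deletion library than in every control library. Control libraries 1, 2 and 3 held 16.1, 16.1 and 15.2 FPKM, and deletion libraries 1, 2 and 3 held 12.5, 13.0 and 14.2 FPKM. The mean went from 15.8 ± 0.56 to 13.2 ± 0.85 FPKM, a change of -16.3% (log2 fold change -0.24, SE 0.066). This did not pass the threshold (adjusted p = 0.0562), and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. It passed under 7 other settings, for example with median-ratio scaling (log2 fold change -0.33, adjusted p = 0.0266), where adjusted p-values over all settings lay between 0.0166 and 0.154. A value per gene also counts fragments from exons outside a floxed part, and which part is floxed is not given in the sources used here, so the value is a weak check of the labels.

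Among the CoREST complex and its partners, 5 of 19 tested genes rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell. Gfi1, a transcriptional repressor that works through CoREST and Kdm1a, rose from 12.1 ± 0.29 to 34.2 ± 3.5 FPKM (log2 fold change 1.42, SE 0.081, adjusted p = 0.000388). Zfp217 rose from 20.6 ± 2.0 to 30.6 ± 1.9 FPKM, Rest from 8.91 ± 0.22 to 11.7 ± 0.51 FPKM, and Zmym3 from 8.42 ± 0.46 to 11.6 ± 0.76 FPKM. The fifth, Zfp516, went from 0.806 to 1.47 FPKM. The subunits themselves did not pass the threshold, though some were higher in every deletion library. Rcor2 went from 0.904 ± 0.076 to 1.36 ± 0.15 FPKM (adjusted p = 0.0915), Kdm1a from 34.5 ± 1.4 to 39.2 ± 1.2 FPKM (adjusted p = 0.0763) and Hdac1 from 119 ± 3.0 to 134 ± 3.3 FPKM (adjusted p = 0.0613). Hdac2 was at 28.3 and 26.9 FPKM and Rcor3 at 4.97 and 5.53 FPKM, with adjusted p-values of 0.351 and 0.453. Camera did not set the list apart from other genes (adjusted p = 0.0972). It did so with no filter on low values (adjusted p = 0.0228), but gave adjusted p = 0.842 with an estimated correlation. Fry put it higher on balance (adjusted p = 0.0197), which was lost with median-ratio scaling (adjusted p = 0.137), and with each library left out in turn 2, 5, 4, 3, 2 and 1 members rose.

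**Figure D1:**
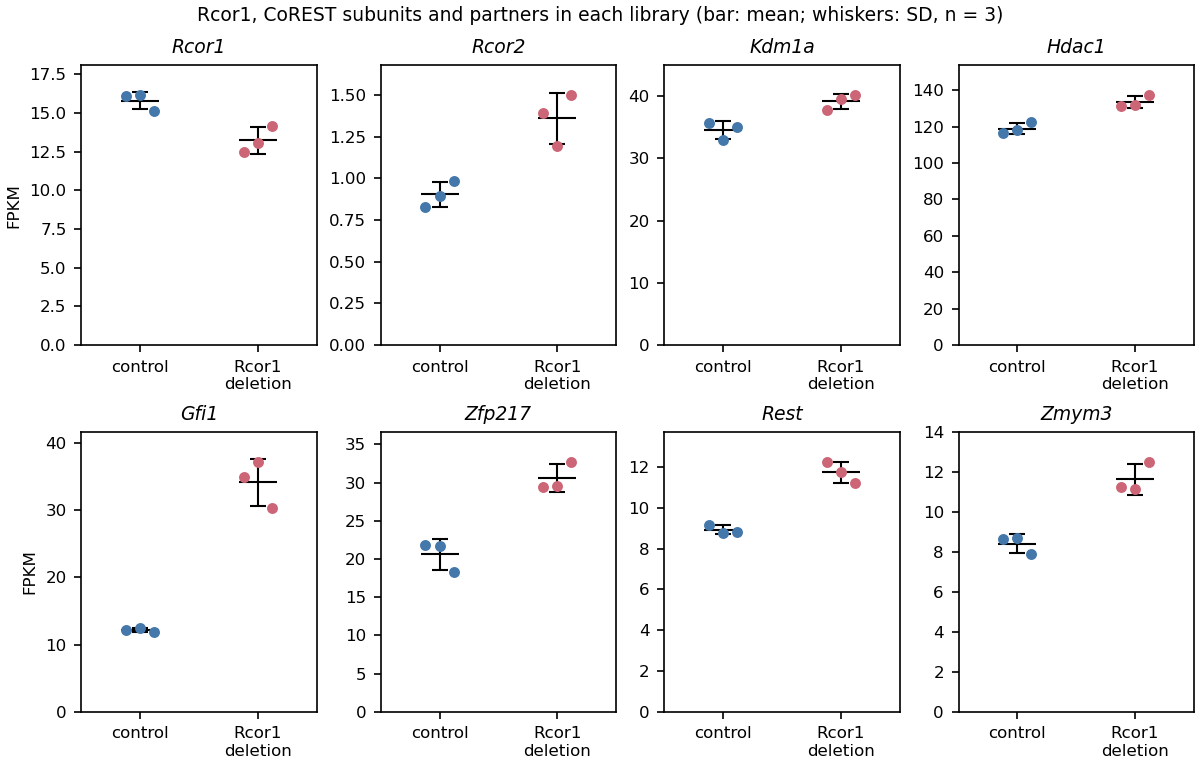
FPKM (vertical axes, from 0) of Rcor1, of other CoREST subunits and of partner proteins in each of the 3 control and 3 Rcor1 deletion libraries, where points are libraries, bars are means and whiskers are SD. Rcor1 lies at 15.8 FPKM in control and 13.2 FPKM in deletion libraries, and Gfi1 at 12.1 and 34.2 FPKM.

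Rcor1 deletion went with many changes of modest size. No batch is given, so a difference in preparation that ran with the groups cannot be told apart from the deletion. Of 11575 tested genes, 1392 changed, of which 1036 (74.4%) rose and 356 fell, and 151 changed at least 2-fold (67 rose and 84 fell). The count at 2-fold or more was 66, 144, 67, 121, 107 and 99 with each library left out in turn, 94 with a filter at 5 FPKM, 83 with a pseudocount of 5 and 81 without receptor segments and pseudogenes. It was higher with a pseudocount of 0.1 (214), array quality weights (199) and voom (193). The genes with the smallest p among those that rose at least 2-fold included ion channel, cytoskeletal and B cell genes. Kcnf1, a potassium channel subunit, rose from 0.596 ± 0.078 to 14 ± 1.5 FPKM. Nrn1, a neuritin first described in neurons, rose from 17.0 ± 2.3 to 49.1 ± 1.0 FPKM, and the kinesin gene Kif1b from 7.78 ± 0.72 to 21.4 ± 1.7 FPKM. Trim46, which organises neuronal microtubules, rose from 1.28 to 4.41 FPKM and the galectin gene Lgals7 from 1.51 to 5.64 FPKM. Fcrl1 and H2-Ob, both typical of B cells, rose from 3.21 to 7.98 FPKM and from 16.0 to 42.0 FPKM, and Ighe, the constant gene of immunoglobulin E, rose from 0.174 to 5.46 FPKM. Adjusted p-values of these genes lay between 1.56e-05 (Kcnf1) and 0.00132 (Ighe).

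The split between rising and falling genes depends on how libraries are scaled, since 43.4% of 1216 changed genes rose with median-ratio scaling, 49.1% of 1429 with voom and 54.5% of 868 with quantile normalization. The count depends on single libraries too, at 315 without control library 1, 529 without control library 3, and 501, 379 and 279 without deletion library 1, 2 and 3, against 1862 without control library 2. Kcnf1, Nrn1, Kif1b, Trim46, Lgals7, Fcrl1, H2-Ob and Ighe stayed past the threshold with any 1 library left out. At an unadjusted p under 0.05 there were 3770 genes, where 579 are expected by chance, and the groups did not overlap in 39.1% of genes, where chance gives 10%.

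**Figure D2:**
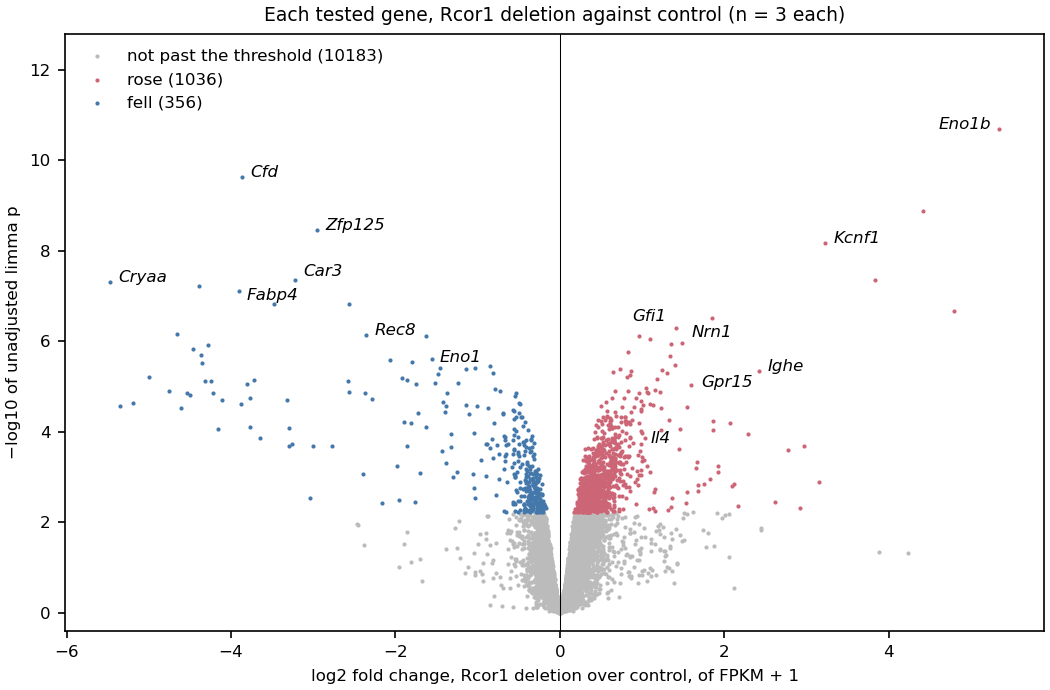
Each of 11575 tested genes by log2 fold change of FPKM + 1 (horizontal axis, Rcor1 deletion over control) and −log10 of the unadjusted limma p (vertical axis), with 1036 genes that rose in red, 356 that fell in blue and the others in grey. Eno1b and Kcnf1 stand out among those that rose, and Cfd, Zfp125 and the crystallin Cryaa among those that fell.

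Eno1b showed the highest log2 fold change of the named genes that rose. It is a near-identical copy of the glycolytic enzyme gene Eno1 and lies on chromosome 18 (48045335 to 48048412). Eno1b rose from 0.745 ± 0.12 to 69.9 ± 2.5 FPKM (log2 fold change 5.35, SE 0.071, adjusted p = 2.35e-07), while Eno1 itself fell from 373 ± 29 to 207 ± 3.8 FPKM (log2 fold change -0.85, adjusted p = 0.00125). Because the counting could divide fragments between these copies, the individual values are uncertain. Their sum was 758.6, 698.3 and 815.1 CPM in control libraries 1, 2 and 3 and 553.2, 541.5 and 529.6 CPM in deletion libraries 1, 2 and 3.

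Transcripts of lens and fat made up most of the named genes that fell at least 2-fold with the smallest p, a choice that left out receptor variable segments. All 13 tested crystallin genes, which encode the structural proteins of the eye lens, fell, with control means of 4.95 to 49.8 FPKM and deletion means of 0 to 0.796 FPKM. Cryaa fell from 49.8 ± 17 to 0.111 ± 0.16 FPKM (adjusted p = 7.01e-05) and Cryba1 from 24.0 ± 6.6 to 0.175 ± 0.13 FPKM. Cryab went from 10.8 to 0.0391 FPKM, and Crybb2 and Cryba2 were at 0 in all deletion libraries, at least 494.4-fold and 95.8-fold lower than in control. Among genes of fat cells, Fabp4, a fatty acid carrier, fell from 25.9 ± 5.4 to 0.783 ± 0.26 FPKM, and Car3, a carbonic anhydrase, from 9.26 ± 1.5 to 0.0972 ± 0.088 FPKM. Cfd, which encodes adipsin, fell from 13.6 ± 0.22 FPKM to 0 in all deletion libraries (at least 262.7-fold lower, adjusted p = 1.36e-06). The zinc finger gene Zfp125 likewise fell from 6.73 ± 0.099 FPKM to 0 (at least 77.0-fold lower), and Rec8, a meiotic cohesin gene, fell from 5.59 ± 1.2 to 0.274 ± 0.086 FPKM. The crystallin falls held with quantile normalization and with median-ratio scaling, with 13 of 13 in each case.

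Of the Treg genes in the panel, Foxp3, Il2ra, Ctla4 and Tnfrsf18 did not pass the threshold, whereas Ikzf2 did. Foxp3 was at 95.6 ± 9.4 and 103 ± 3.1 FPKM (adjusted p = 0.348), Il2ra at 137 ± 7.9 and 148 ± 8.4 FPKM (adjusted p = 0.295), Ctla4 at 209 ± 36 and 219 ± 33 FPKM (adjusted p = 0.764) and Tnfrsf18 at 42.9 ± 5.8 and 41.2 ± 2.0 FPKM (adjusted p = 0.753) in control and deletion libraries. Within the Treg signature, 6 of 26 genes rose and 1 fell, and adjusted over the list alone 8 rose and 3 fell. Gpr15, a receptor that directs T cells to the large intestine, rose from 6.64 ± 0.61 to 22.4 ± 4.7 FPKM (log2 fold change 1.60, SE 0.14, adjusted p = 0.00178). Itgae, the integrin chain CD103, rose from 40.2 ± 2.4 to 61.7 ± 9.4 FPKM and the ectonucleotidase gene Entpd1 from 8.08 ± 0.43 to 10.9 ± 0.88 FPKM. Ikzf2, which encodes Helios, rose from 47.5 ± 5.9 to 62.5 ± 3.9 FPKM (adjusted p = 0.0463), a call lost without any library other than control library 2, with both scalings and with voom. Il2rb, a subunit of the IL-2 receptor, fell from 379.7 ± 4.9 to 299.6 ± 12 FPKM (adjusted p = 0.00968). With median-ratio scaling the split of this list was 2 that rose and 3 that fell. Leaving out each library in turn gave 1, 6, 2, 2, 2 and 2 that rose, and the changes of Gpr15 and Il2rb held each time. Camera did not set the list apart (adjusted p = 0.604).

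Of 25 effector Treg genes, 4 rose and 1 fell, with the same counts adjusted over the list alone. The alarmin receptor gene Il1rl1 rose from 7.08 ± 0.26 to 9.73 ± 0.091 FPKM, and Fgl2, a secreted suppressive mediator, fell from 13.4 ± 0.83 to 7.33 ± 0.91 FPKM (adjusted p = 0.00493). Il10 was at 10.1 ± 3.4 and 10.9 ± 3.1 FPKM (adjusted p = 0.793). With each library left out in turn 1, 4, 3, 2, 2 and 0 effector genes rose, the fall of Fgl2 held, and camera did not set the list apart (adjusted p = 0.858). Genes of resting and central T cells lay lower than other genes by camera (adjusted p = 0.0074), though adjusted p = 0.842 with an estimated correlation and 0.136 with quantile normalization. The call was also lost without control library 2 (adjusted p = 0.0681) or deletion library 2 (adjusted p = 0.183). Within this list of 18, Ccr7, the lymph node homing receptor, fell from 205 ± 20 to 139 ± 7.4 FPKM and Igfbp4 from 115 ± 14 to 63.1 ± 8.7 FPKM, while Id3, an inhibitor of E proteins, rose from 36.7 ± 5.2 to 61.3 ± 9.2 FPKM. The counts of 1 that rose and 2 that fell held adjusted over the list alone. Without a given library the falls of Ccr7 and Igfbp4 held, and the rise of Id3 held only without control library 2.

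**Figure D3:**
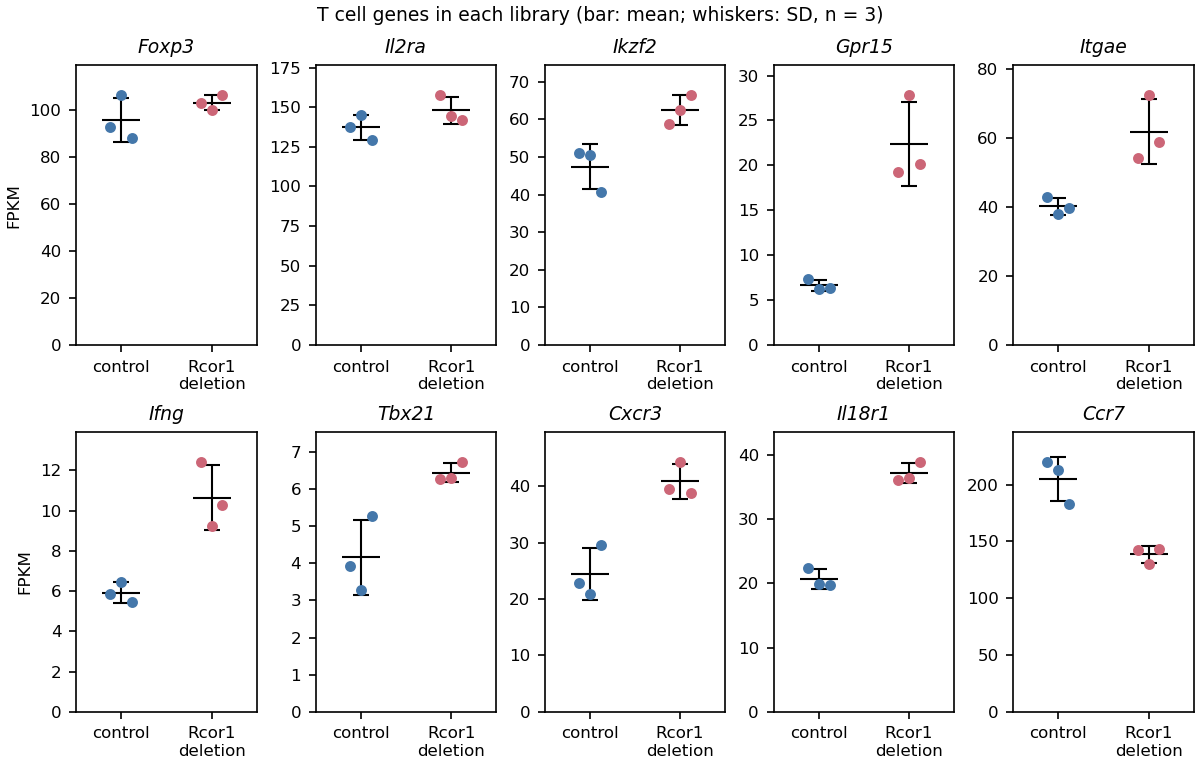
FPKM (vertical axes, from 0) of 10 T cell genes in each of the 3 control and 3 Rcor1 deletion libraries, where points are libraries, bars are means and whiskers are SD. Foxp3 lies at 95.6 and 103 FPKM, whereas Gpr15 lies at 6.64 and 22.4, Ifng at 5.92 and 10.7, and Ccr7 at 205 and 139 FPKM.

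Genes of T helper type 1 (Th1) cells rose in part, with 6 of 19 that rose and 0 that fell, and 6 and 1 adjusted over the list alone. Ifng, which encodes interferon gamma, rose from 5.92 ± 0.50 to 10.7 ± 1.6 FPKM (log2 fold change 0.74, SE 0.11, adjusted p = 0.0114). The IL-18 receptor gene Il18r1 rose from 20.7 ± 1.5 to 37.2 ± 1.5 FPKM (adjusted p = 0.00153), the chemokine receptor gene Cxcr3 from 24.4 ± 4.6 to 40.9 ± 3.0 FPKM, and Tnf from 14.1 ± 2.9 to 25.2 ± 3.6 FPKM. Tbx21, the Th1 master regulator T-bet, rose from 4.17 ± 1.0 to 6.44 ± 0.25 FPKM (adjusted p = 0.0479), a call lost without any library other than control library 3 and with quantile normalization or median-ratio scaling. Il2 was at 1.41 ± 0.23 and 1.33 ± 0.27 FPKM (adjusted p = 0.807). Fry put the list higher on balance (adjusted p = 0.0339, and 0.137 with median-ratio scaling), whereas camera did not (adjusted p = 0.149). Camera did set it apart with median-ratio scaling (adjusted p = 0.0407), no filter on low values (0.0285), a filter at 5 FPKM (0.0482) and without control library 3 (0.0468). With all libraries camera gave adjusted p = 0.842 with an estimated correlation. With each library left out in turn 1, 5, 5, 2, 2 and 1 members rose. The rise of Il18r1 held each time, and that of Ifng was lost without control library 1 (adjusted p = 0.0531) or deletion library 3 (adjusted p = 0.0518).

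For the other helper programmes the counts were smaller. Il4, the T helper type 2 (Th2) cytokine gene, rose from 1.29 ± 0.16 to 3.56 ± 0.65 FPKM (adjusted p = 0.00629), and with Il1rl1 made 2 of 8 Th2 genes that rose. Il4ra, its receptor, fell from 53.4 ± 2.3 to 44.9 ± 2.5 FPKM. Adjusted over the list alone, 3 Th2 genes rose and 1 fell. Of 7 Th17 genes, 0 passed limma's test or voom, and 1 had an unadjusted p under 0.05 (Rora, at 4.78 and 6.40 FPKM). Adjusted over the list alone, 0 passed. Follicular helper (Tfh) genes rose in 5 of 12 cases, 6 of 12 adjusted over the list alone, including Tox from 21.1 ± 0.52 to 27.1 ± 0.52 FPKM, Slamf6 from 66.7 ± 3.4 to 86.1 ± 3.6 FPKM, Btla from 34.7 to 41.5 FPKM and Tox2 from 5.11 to 7.61 FPKM. With each library left out in turn 1, 4, 2, 2, 1 and 0 of them rose, and 2 rose with median-ratio scaling. Il4ra lost its call whichever library was left out, while Il4 kept it. Camera's adjusted p was 0.837 for Th2, 0.604 for Th17 and 0.312 for Tfh genes.

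Among chemokine and homing receptors, 4 of 22 rose (Gpr15, Cxcr3, Itgae and Itga4) and 1 fell (Ccr7), with the same counts adjusted over the list alone and a camera adjusted p of 0.565, and 2, 4, 3, 2, 2 and 1 rose with each library left out in turn. Immediate early genes, which respond to activation and also to the handling of cells, rose in 6 of 16 cases and fell in 0, and adjusted over the list alone 7 rose and 1 fell. Fosb rose from 37.6 ± 2.3 to 76.6 ± 15 FPKM, Fos from 133 ± 16 to 218 ± 18 FPKM, Jun from 112 ± 17 to 169 ± 2.8 FPKM and Jund from 152 ± 11 to 203 ± 6.1 FPKM. Camera's adjusted p for this list was 0.154, and 0.0202 with quantile normalization, 0.0356 with no filter on low values and 0.0197 without control library 2. It gave adjusted p = 0.842 with an estimated correlation, and 3, 8, 4, 3, 3 and 2 members rose with each library left out in turn. Of 18 genes of the T cell receptor (TCR) response, Nr4a1 rose from 95.5 ± 22 to 161 ± 5.8 FPKM and Egr3 from 14.9 ± 1.6 to 21.7 ± 1.6 FPKM, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.561), whereas 2 rose and 2 fell with median-ratio scaling. Of them 0, 4, 1, 1, 0 and 1 rose with each library left out in turn. The IL-2 and STAT5 response held 2 of 18 genes that rose, Pim1 from 134 to 177 FPKM and Osm from 11.7 to 15.8 FPKM, and 1 that fell, Il2rb, against 3 and 2 adjusted over the list alone. The median log2 fold change of this list was 0.07, whereas camera's direction was downward (adjusted p = 0.85), and with median-ratio scaling 1 rose and 2 fell. Of these genes 0, 4, 0, 1, 0 and 0 rose with each library left out in turn. Of 24 type I interferon response genes 0 passed with limma, with voom or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.618). Ifit2 was at 17.4 and 20.8 FPKM and Stat2 at 19.1 and 25.9 FPKM. Of 23 apoptosis regulators Pmaip1 rose from 5.60 to 8.39 FPKM and Fas from 25.7 to 31.6 FPKM, likewise 2 adjusted over the list alone, but quantile normalization turned the split to 0 that rose and 2 that fell. Median log2 fold change was 0.04 and camera pointed downward (adjusted p = 0.618), and with each library left out in turn 0, 2, 1, 1, 0 and 0 rose.

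**Figure D4:**
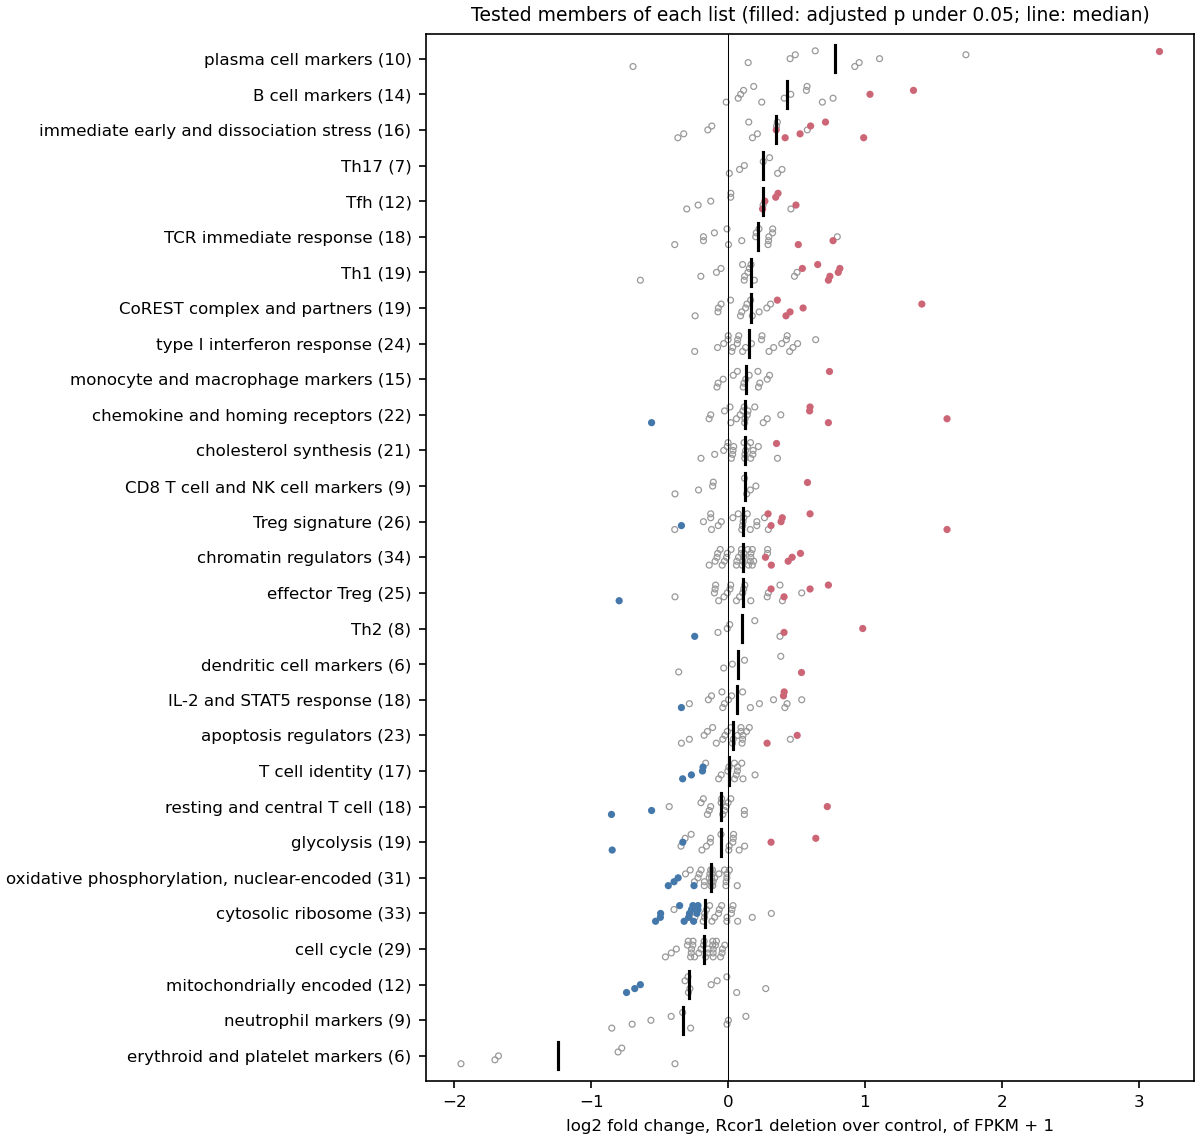
Log2 fold change of FPKM + 1 (horizontal axis, Rcor1 deletion over control) of the tested members of 29 fixed lists, ordered by median (black line), with filled points for members at an adjusted p under 0.05 and the number tested in parentheses. Median values run from -1.24 for erythroid and platelet markers to 0.78 for plasma cell markers, where 0 and 1 members passed.

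Some genes of the ribosome and of respiration fell. Of 33 cytosolic ribosomal protein genes 13 fell and 0 rose, and adjusted over the list alone 19 fell. Rps24 fell from 2418 ± 23 to 1718 ± 58 FPKM, Rpl37 from 1113 ± 60 to 771 ± 47 FPKM, Rps14 from 4159 ± 332 to 2944 ± 20.1 FPKM and Rplp2 from 1441 ± 62 to 1127 ± 21 FPKM. Camera placed the list below other genes (adjusted p = 1.64e-11), but not with an estimated correlation (unadjusted p = 0.06, adjusted p = 0.842). With quantile normalization the list's direction reversed (median log2 fold change 0.05, camera adjusted p = 0.136). Of all 81 tested ribosomal protein genes, a class examined after its values were seen, 45 fell and 1 rose (median log2 fold change -0.25), and with quantile normalization 14 fell and 4 rose (median -0.063). Of 31 nuclear genes of oxidative phosphorylation 4 fell and 0 rose, also adjusted over the list alone, for example Cox7a2 from 84.2 ± 7.5 to 63.6 ± 0.73 FPKM and Ndufb9 from 94.3 ± 7.4 to 73.0 ± 6.4 FPKM. Ndufb7 and Uqcrh were the others, at 21 and 15.2 FPKM and at 196 and 165 FPKM. Camera gave an adjusted p of 2.38e-08 for them, and adjusted p = 0.842 with an estimated correlation. Of 12 mitochondrially encoded transcripts 3 fell, also adjusted over the list alone, namely mt-Nd1 (2941 ± 330.2 to 1760 ± 215 FPKM), mt-Nd2 (1525 ± 143 to 955 ± 146 FPKM) and mt-Nd6 (1139 ± 156 to 729 ± 92 FPKM). Camera's adjusted p was 0.00059, and adjusted p = 0.842 with an estimated correlation, and with quantile normalization 0 members passed and camera's adjusted p was 0.184. With each library left out in turn 4, 14, 5, 7, 4 and 2 ribosomal, 0, 6, 1, 0, 0 and 0 oxidative phosphorylation and 1, 3, 2, 4, 1 and 0 mitochondrially encoded genes fell.

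Signs of library composition moved with the groups, and whether preparation or the deletion lay behind them cannot be told. Mitochondrially encoded genes took 2.23%, 1.92% and 1.87% of fragments in control libraries 1, 2 and 3 and 1.81%, 1.35% and 1.49% in deletion libraries 1, 2 and 3. Gm42418, a gene that overlaps a ribosomal RNA repeat and was chosen after its values were seen, was at 3024, 2008 and 2344 FPKM in control and 538, 558 and 645 FPKM in deletion libraries.

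In glycolysis, 2 of 19 genes rose and 2 fell, with the same counts adjusted over the list alone and a camera adjusted p of 0.0794, which was 0.000528 without control library 2 and 0.043 without deletion library 2, but adjusted p = 0.842 with an estimated correlation. Slc2a3, a glucose transporter gene, rose from 13.2 ± 0.085 to 21.2 ± 0.48 FPKM (adjusted p = 0.00132) and Pfkp from 29.5 ± 2.1 to 36.9 ± 0.72 FPKM. Aldoa fell from 267 ± 26 to 212 ± 10 FPKM, next to Eno1. The changes of Slc2a3 and Eno1 held with any 1 library left out, whereas Aldoa kept its call only without control library 2. Cell cycle genes were lower as a list by camera (adjusted p = 0.00059), and adjusted p = 0.842 with an estimated correlation. Without control library 3 this call was lost (adjusted p = 0.14) and the list's median log2 fold change went from -0.18 to -0.002, against -0.39 without control library 2 and -0.34 without deletion library 2. All 29 had lower means in the log2 fit of all libraries, yet 0 passed with limma or voom, 0 adjusted over the list alone and 0 had an unadjusted p under 0.05. Mcm4 was at 45.2 ± 7.8 and 37.4 ± 4.2 FPKM and Mcm7 at 57.0 ± 9.9 and 48.8 ± 6.1 FPKM. Of 21 genes of cholesterol synthesis 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.539), while 0 rose with median-ratio scaling and 0, 1, 0, 0, 0 and 1 with each library left out in turn. Of 34 other chromatin regulators 5 rose and 0 fell, with 6 that rose adjusted over the list alone. They include the deacetylase gene Sirt1 (7.46 ± 0.61 to 10.7 ± 0.22 FPKM), Mbd2 (112 ± 3.1 to 140 ± 5.4 FPKM), the demethylase gene Kdm6b (28.6 ± 2.7 to 39.1 ± 0.81 FPKM) and Tet1 (0.958 ± 0.23 to 1.81 ± 0.11 FPKM). Fry's adjusted p for them was 0.00234 and 0.244 with median-ratio scaling. Camera's was 0.149, and 0.0184 with no filter on low values, but adjusted p = 0.842 with an estimated correlation. With each library left out in turn 1, 5, 3, 2, 0 and 0 rose. Only 4 of 26 neuronal genes regulated by Rest were expressed highly enough to test, and 0 passed with limma or voom, also adjusted over the list alone, while 2 had an unadjusted p under 0.05. L1cam was at 5.97 and 7.41 FPKM.

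Markers of cells that the column and gate could let through were also measured. T cell identity genes included 4 of 17 that fell, also adjusted over the list alone, and 0 that rose, with Cd2 from 506 ± 20 to 420 ± 10 FPKM, Thy1 from 420 ± 8.5 to 369 ± 5.7 FPKM, Cd247 from 76.6 ± 5.7 to 60.6 ± 5.0 FPKM and Cd3g from 528 ± 8.9 to 465 ± 7.7 FPKM. Quantile normalization turned this split to 3 that rose and 1 that fell, and with each library left out in turn 1, 1, 0, 0, 0 and 0 fell. The list's median log2 fold change was 0.006 and its mean -0.033, and camera pointed downward (adjusted p = 0.0942). Camera did place this list lower with median-ratio scaling (adjusted p = 0.012), with voom (0.00958), without segments and pseudogenes (0.0251), and without control library 1 (0.028), control library 3 (0.0157) or deletion library 1 (0.0489). For all libraries it gave adjusted p = 0.842 with an estimated correlation. Of 14 B cell markers 2 rose, also adjusted over the list alone. Cd22 rose from 2.04 ± 0.54 to 5.17 ± 0.23 FPKM and Ighm from 800.4 ± 392 to 1894 ± 229 FPKM, while Cd79a was at 10.7 ± 4.6 and 15.4 ± 1.5 FPKM, not past the threshold. Camera's adjusted p was 0.154, and 0.0312 with median-ratio scaling, 0.0413 with quantile normalization and 0.00114 without control library 3, but adjusted p = 0.842 with an estimated correlation. With each library left out in turn 1, 2, 2, 1, 1 and 1 rose, with Cd22 past the threshold each time. Of 10 plasma cell markers 1 rose, also adjusted over the list alone, Ighg1 from 15.4 ± 17 to 104 ± 10 FPKM. Without control library 2, where Ighg1 was at 34.7 FPKM against 5.33 and 6.31 FPKM in control libraries 1 and 3, 8 of these markers rose, and without any other library 0 did. Camera's adjusted p was 0.149, and 0.0186 with median-ratio scaling, 0.0202 with quantile normalization, 0.0412 with no filter on low values and 1.48e-05 without control library 2. It gave adjusted p = 0.842 with an estimated correlation.

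Single genes rose on 3 further marker lists, also adjusted over each list alone. They were Crtam among 9 markers of CD8 T and NK cells (1.79 to 3.17 FPKM), Cybb among 15 markers of monocytes and macrophages (6.58 to 11.7 FPKM), and Tcf4 among 6 of dendritic cells (1.07 to 1.98 FPKM), with camera adjusted p-values of 0.604, 0.837 and 0.85. Camera pointed downward for the first 2 lists, where medians were 0.12 and 0.13, but upward for the monocyte list without deletion library 1 (adjusted p = 0.0155), against adjusted p = 0.951 for all libraries with an estimated correlation. Each of these calls was lost without control library 1 or deletion library 2 or 3, and that of Tcf4 also without deletion library 1. Of 9 neutrophil and 6 erythroid and platelet markers 0 passed with limma, voom, an unadjusted p under 0.05 or adjusted over the list alone. These markers varied within groups. S100a8 was at 2.60, 32.7 and 76.1 FPKM in the control libraries and at 0.342, 144 and 10.2 FPKM in the deletion libraries, and S100a9 at 41.3 ± 37 and 54.3 ± 86 FPKM. Hba-a1 was at 81.8 ± 76 and 17.3 ± 13 FPKM and Hba-a2 at 11.3 ± 9.4 and 2.27 ± 1.8 FPKM. Camera's adjusted p was 0.312 for neutrophil markers and 0.0188, lower in deletion, for erythroid and platelet markers, with adjusted p = 0.842 with an estimated correlation and 0.103 with median-ratio scaling. The erythroid and platelet call was also lost without control library 2 (adjusted p = 0.111), control library 3 (0.14) or deletion library 3 (0.0912). Neutrophil markers were placed lower without control library 1 (0.0378) or deletion library 2 (0.0129), and camera pointed upward without deletion library 1 (0.906), against adjusted p = 0.903 for all libraries with an estimated correlation.

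Variable segments of the immunoglobulin heavy chain, a class examined after its values were seen, changed in both directions. They lie on chromosome 12 between 113578504 and 116000461, within 10 Mb of Rcor1. Of 85 tested segments 29 fell and 10 rose, and groups did not overlap in 58.8%, against 39.1% of all tested genes, 20.5% of kappa and 20% of T cell receptor variable segments, where chance gives 10%. Kappa light chain variable segments gave 9 of 78 that rose and 0 that fell, and T cell receptor variable segments 1 of 95 that rose and 5 that fell. With median-ratio scaling the heavy chain counts were 29 and 9, and with quantile normalization 27 and 8. Homologous segments can share fragments, so single segments are uncertain.

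**Figure D5:**
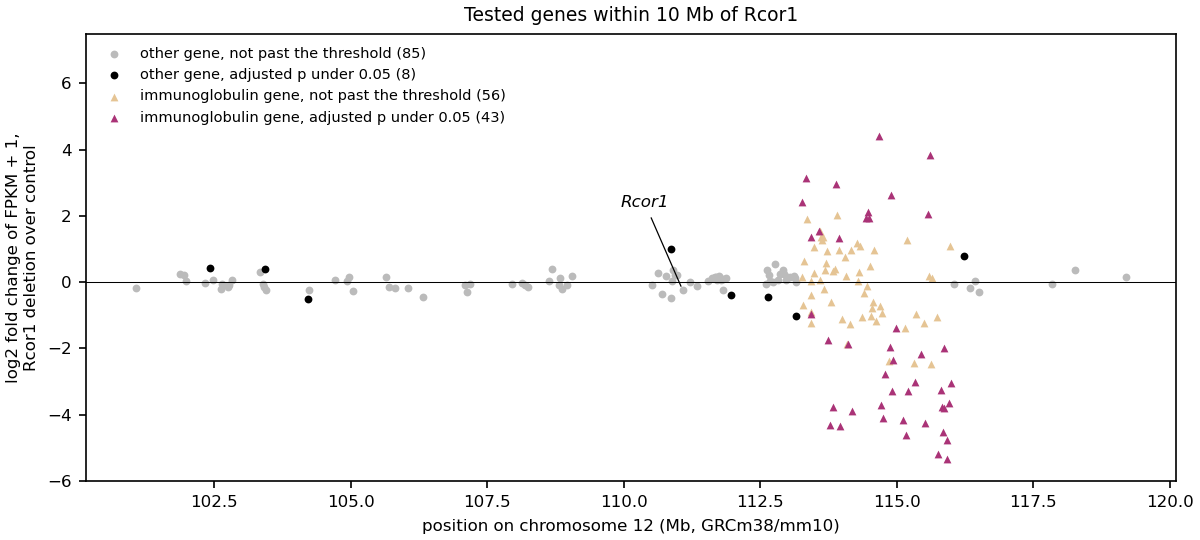
Log2 fold change of FPKM + 1 (vertical axis, Rcor1 deletion over control) of tested genes within 10 Mb of Rcor1 by position on chromosome 12 (horizontal axis, Mb), with immunoglobulin genes as triangles and other genes as circles. Immunoglobulin genes past the threshold lie on either side of 0, and 8 of 92 other genes besides Rcor1 passed.

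The libraries of a group resembled each other more than those of the other group. Pearson correlations over the tested genes were 0.984 to 0.987 within control, 0.985 to 0.989 within deletion and 0.962 to 0.969 between groups, taken across genes, which are not independent replicates. The first principal component held 58.2% of the variance and separated the groups, and the second held 13.9%. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.12 to 19.01. They were counted as separate samples because the series' design text describes them as independent.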

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

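The tests on recovered fragments, without receptor segments and pseudogenes, and with length or GC trends removed were chosen after the data were seen. The planned quasi-likelihood count test on recovered reads was not run. Against 1392 changed genes, counts were 279 to 1862 with 1 library left out, 404 with the replicate block, 844 with no filter, 868 with quantile normalization, 2396 with array quality weights, 151 at 2-fold or more and 161 by treat against 1.2-fold. The other alternatives gave 1147 to 1672. No gene called in common changed sign. The counts at 2-fold and by treat are lower by construction, and for the rest the cause was not tested. Same-numbered libraries did not deviate together (correlations of 0.211, -0.135 and -0.162), so the number was no evidence of pairing and the block result is a value only. The number is that of the sample titles, and the deposited deletion columns carry other numbers in their names.

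Rcor1 stayed lower in all settings, with log2 fold changes from -0.288 to -0.204 with 1 library left out. It passed the threshold at the 5 FPKM filter (-0.241, adjusted p = 0.0492), with quantile normalization (-0.331, 0.0314), median-ratio scaling (-0.331, 0.0266), array quality weights (-0.247, 0.0358), voom (-0.346, 0.0166), without segments and pseudogenes (-0.241, 0.0473) and with the length trend removed (-0.268, 0.0472). Against 6 lists past camera's threshold there were 11 with no filter, 10 with voom, 5 to 8 with 1 library left out and 0 with an estimated correlation. The ribosomal list reversed with quantile normalization (adjusted p = 0.136), while the median of all 81 ribosomal protein genes was -0.063 (14 fell and 4 rose), and the cause was not tested.

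Of 2084 values of named genes under alternatives 1730 kept direction and side of the threshold, 328 lost the call, 10 gained it and 16 changed sign. Of 84 called named genes 31 were never lost and 50 were lost when some library was left out, 42, 8 and 25 without control library 1, 2 and 3 and 31, 41 and 47 without deletion library 1, 2 and 3. The sign changes were all in genes not past the threshold, and their cause was not tested. With 1 library left out, log2 fold changes ran from -0.086 (-0.067 without control library 1) to 0.341 for Il10, from -0.145 to 0.047 for Tnfrsf18, from -0.042 (-0.007 without deletion library 3) to 0.205 for Ctla4, from -0.135 to 0.048 for Il2, from -2.656 to 0.768 (0.032 without control library 3) for S100a9 and from -2.441 to 0.935 (0.235 without control library 3) for S100a8. With array weights Tnfrsf18 was at 0.033, Il2 at 0.031, S100a9 at 0.487 and S100a8 at 0.543, and Ctla4 was at -0.021 with median-ratio scaling and -0.014 with voom. Depth limits genes near the filter, where few fragments back a value.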

Other observations

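Tests chosen only after the result was seen are those of a single source of lens and fat transcripts, all tests of heavy chain segments, and those of gene length and library scaling for ribosomal genes. The test of abundant transcripts as a class was set after the reversal with quantile normalization had been seen, and its repeats on all ribosomal protein genes after their median had been seen. The shares of all detected genes beside the lens, fat and intestinal lists were likewise added after those lists' results. Joining segments of the T cell receptor, a class examined after its values were seen, rose in 14 of 57 tested cases and fell in 1, with a median log2 fold change of 0.62, against 13 and 1 with median-ratio scaling, 12 and 1 with quantile normalization, 8 and 0 with voom, and 9 and 2 with the length trend removed, where the median was 0.405. Ighe and Ighg1, constant genes of switched immunoglobulins, rose from 0.174 to 5.46 and from 15.4 to 104 FPKM, whereas Igha was at 629 ± 443 and 615 ± 169 FPKM and Ighg2c at 40.4 ± 31 and 20.6 ± 9.0 FPKM in control and deletion libraries. Of 11220 tested genes other than receptor segments, 25 were at 3 fragments or fewer in all deletion libraries and at 10 or more in all control libraries, and 0 the other way round. Most of the named ones among these 25 were crystallins, fat genes (Cfd, Ucp1, Retn, Cidec) and genes of intestinal epithelium (Agr2, Clca1).

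Nrn1, Kcnf1 and Trim46 raised the hypothesis that neuronal and synaptic genes were higher as a class. A second list of 92 such genes was fixed before it was tested, and 36 of them were expressed highly enough. Of these 11 rose (Sema4f, Grik5, Homer1, Vamp2, Gabbr1, Cacna1a, Camk2n1, Kcna3, Kcnn4, Dlgap4 and Syt11) and 1 fell (Camk2b). The median log2 fold change of 0.31 lay at percentile 100 of 10000 random lists matched on expression, whose central range was 0.026 to 0.191. For the fixed list of Rest-regulated neuronal genes, 23 could be tested with no filter on low values. Camera did not set them apart (adjusted p = 0.489). The median of the second list goes with the hypothesis, which itself came from genes of these same libraries. The percentile overstates the evidence, because the random lists draw genes one by one, unlike genes that move together. The matching removes a shift shared by all genes, but not one tied to transcript length. Whether it comes from the Treg cells themselves was not tested.

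The count of 1392 changed genes was compared with other splits of the 6 libraries into 3 and 3. The 10 splits are too few for a share under 0.05. The real split gave 1392 genes, as 1 of 10, and the highest count of the other splits was 0. Every other split mixes control with deletion libraries, so a group difference of any cause enters its spread and lowers its count. The contrast of counts therefore says nothing of what caused the difference.

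The first pattern is the lens and fat transcripts of control libraries. Fragments of the 13 crystallins made up 204, 364 and 167 CPM in control libraries 1, 2 and 3 and 1.70, 1.38 and 1.58 CPM in deletion libraries 1, 2 and 3, and a set of 6 fat genes 56.5, 64.8 and 68.5 CPM against 0.81, 2.61 and 2.77 CPM. RNA of other tissues in the control libraries may account for this, since many genes of those tissues were higher in every control library than in every deletion library. They were 46.2% of 13 detected lens genes other than crystallins (Mip and Bfsp1 among them), 93.8% of 16 brown fat genes (Scd1 at 11.2 and 1.47 FPKM) and 80% of 15 genes of intestinal epithelium (Zg16 at 2.87 and 0 FPKM). Of all 17331 detected genes 9.47% were (one-sided Fisher's exact p of 0.000682, 6.07e-15 and 1.74e-10). These p-values overstate the evidence, because they treat genes as independent, though genes of a tissue would move together. Detection was by fragments summed over all libraries, so a gene seen in control libraries alone could count. Whether lens and fat RNA had a single source stays open, as the log2 ratio of control library 2 to 3, libraries picked after their values were seen, had a median of 1.16 for crystallins and -0.18 for fat genes, a difference of 1.33 over genes that are not independent. The CD4 column and the sort on YFP would remove such cells, 7 of the 13 lens genes were not so separated (Capn3 at 11.5 and 12.3 FPKM), and the route of entry stays open, as does an effect of Rcor1 deletion itself, which was not tested.

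The second pattern is the heavy chain segments next to Rcor1. More B cell RNA in deletion libraries cannot alone account for it, since 34.1% of the tested heavy chain variable segments fell. Groups did not overlap in 58.8%, against 20.5% of kappa and 20% of T cell receptor variable segments and 39.1% of all tested genes. A few clones per library would make segments vary within groups too, but the limits of that test were chosen after the data were seen. It therefore cannot decide on clones, which stay open. The first test of another haplotype carried along with the floxed allele, made on neighbouring genes, cannot decide it. Genes other than immunoglobulin genes within 10 Mb of Rcor1 passed in 8.7% of 92 cases against 11.8% elsewhere (one-sided Fisher's exact p = 0.861, odds ratio 0.714, upper 95% bound 1.48). This narrowly met the limit set against the haplotype, but that limit was chosen after the data were seen. Shares of genes that passed and changed at least 1.5-fold were 3.3% and 2.9% (one-sided Fisher's exact p = 0.505). A haplotype that changes few of these genes would not raise such a share. A haplotype that differs within the heavy chain locus itself also stays open. These data cannot decide it, because its measure and fragment limits were chosen after that first result and after segment values were seen. By that measure 22.4% of segments (19 of 85, 17 of them in control only) were at 3 fragments or fewer in every library of one group and at 10 or more in every library of the other, against 0 of 173 kappa and T cell receptor segments (one-sided Fisher's exact p = 1.54e-10), while the strain background is not given in the sources used here and an effect of Rcor1 deletion was not tested.

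The third pattern is the lower ribosomal protein transcripts. Relative to all genes the list's median was -0.25, and it stayed at -0.199 with the length trend removed and -0.233 with the GC trend removed (camera adjusted p of 3.49e-08 and 5.94e-11, but adjusted p = 0.859 and 0.844 with an estimated correlation), which by the median alone argues against each of these as the whole cause. Median-ratio scaling left it at -0.262, which decides nothing on library scaling, since 1 factor per library moves the list and other genes alike, whereas quantile normalization took it to 0.053. As log2 fold changes not set against all genes, the list's median of -0.17 lay at percentile 21.1 of 10000 lists of other genes matched on mean expression (central range -0.268 to 0.025), so a lower level of abundant transcripts as a class stays open for these 33 genes. The median of all 81 tested ribosomal protein genes, -0.25, lay at percentile 0.07 (central range -0.215 to 0.01). With quantile normalization it was -0.063, at percentile 0 (-0.014 to 0.173). Only 30 of the 81 had matches close in expression, within 0.1 on the log2 scale. The median of these 30 was -0.234, at percentile 0.34 (-0.214 to 0.03). With quantile normalization 30 closely matched genes had a median of -0.11, at percentile 0.19 (-0.084 to 0.109). The wider class lay below nearly all matched lists, but it was chosen after its median was seen. The matched lists also draw genes one by one, unlike genes that move together, so these percentiles may be too extreme. They cannot decide the question, and a lower level of abundant transcripts stays open for the wider class too. An effect of Rcor1 deletion was not tested apart from the group comparison itself.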
